A study of Homo sapiens with 5 samples.

How the data were processed

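Total RNA from 5 samples of the human prostate cancer cell lines VCaP and LNCaP was labelled with biotin and measured on 5 gene expression arrays, per the labels. Each sample forms a group of its own: VCaP with control siRNA, VCaP with siRNA against ERG, LNCaP with a LacZ control, LNCaP with ERG overexpression and control siRNA, and LNCaP with ERG overexpression and siRNA against LEF1. The groups were taken from the sample titles. Each group has 1 array and there is no replicate, so no spread between replicates could be estimated, no test was run and no p-value between groups is given. Every fold therefore compares 2 arrays, not 2 conditions, and the number of arrays limits the precision.

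The authors used GenomeStudio, per the submitters' processing notes, in a version not given in the sources used here. The deposited gene-level signals are intensities on a linear scale, background-subtracted and therefore partly below 0, in one table that the authors quantile-normalized between the 5 arrays and in one they did not normalize. Signals in the quantile-normalized table ran from -26.2 to 17840.9. The tables hold 34596 gene entries and 92 entries for spiked-in control RNAs, none of which was detected on any array. The controls were left out. Per the file headers, each signal comes with a detection p-value, which compares it with negative control probes. The detection p-values of the 2 tables differed in 8 entries. A further deposited table holds intensities of 47317 probes without detection p-values and without gene names. Of its rows, 26220 matched the 5 values of a row of the quantile-normalized gene table within 0.05 and 0 matched the table that was not normalized. Its values were therefore taken as quantile-normalized and background-subtracted probe intensities on a linear scale, with array medians of 8.4 to 8.5. It served for counts of probes only. The array type, the genome build and the scan dates are not given in the sources used here, so batches could not be examined and no coordinates are printed.

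A gene was called detected on an array where its detection p-value was under 0.01. This held for 9812 genes on the VCaP control array, 10076 on the VCaP siERG array, 8587 on the LNCaP LacZ array, 9673 on the LNCaP ERG array with control siRNA and 10920 on the LNCaP ERG array with siLEF1. In the table without normalization, mean signals were 142, 128, 112, 156 and 232 in the same order, so the LacZ array was the dimmest and the siLEF1 array the brightest. Quantile normalization gave means of 156 to 158 on all 5. The lowest signal of a detected gene was 10.2, 11.4, 10.2, 10.1 and 5.4. A gene that several probes measure has a single detection p-value, and such a gene can carry a bright signal and miss the threshold. KLK3 missed it on both VCaP arrays, with signals of 130.5 and 246.9.

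Folds are ratios of quantile-normalized signals between the arrays of a comparison. On an array that did not detect a gene, its signal was replaced by the higher of its own value and the lowest detected signal of that array. The fold is then called a lower limit and is written "at least". It is nominal, because a gene can miss detection at a signal above the lowest detected one. FEV did so at 30.5 on the LacZ array and E2F1 at 22.2 on the LNCaP ERG array. The actual fold of an undetected gene can therefore be smaller than the value given. Genes detected on neither array have no fold. A gene counted as higher or lower where the fold was at least 2 and the brighter array detected it at or above the 25th percentile of detected signals, which was 47.9, 44.3, 65.3, 49.2 and 36.6 in the order above. Members of gene lists were counted with the same rule at 1.5-fold. A further condition fixed in advance, a difference over 3 times the bead standard error, was not applied because the tables used here give no such error. Over all genes with a fold, the median log2 fold was 0.016, 0.011 and -0.0014 in the 3 comparisons, and the spread of log2 folds across genes, estimated from the median absolute deviation, was 0.38, 0.69 and 0.49.

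Before the data were examined, 25 gene lists, the comparisons, the size rules and the rule for named genes were fixed. The lists were written from general knowledge of these cells, and the list of genes linked to ERG before was written from memory of the field. All 436 list entries were found in the tables by symbol or alias. For each list with at least 3 detected members, the median log2 fold was set among 10000 random gene lists of the same size, matched on mean signal in 10 bins. A list in the outermost 2.5% on either side is said to lie outside the middle 95% of random lists. This describes these arrays and is no test of the conditions. The medians include genes at their lower limit. Named are ERG and LEF1, the 12 highest and 12 lowest genes per comparison that were also at least 1.5-fold the same way in the scaled table without normalization, up to 4 members per list by size of fold, Wnt ligands, receptors and targets past 1.5-fold, and for overlaps the 8 genes with the largest smaller fold. Entries with provisional names were left out of this naming, and a few genes that the rule names are not reported here. Gene symbols are those of the tables. Entrez identifiers matched 24087 of the 34596 entries to a current RefSeq gene table, used for names only, in which 6419 symbols differed, and 27 symbols in the tables had been turned into dates.

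The comparison of ERG overexpression with LEF1 knockdown shares the ERG array with control siRNA. Chance overlap was therefore simulated 100 times with no effect, with noise per array of 0.29 on the log2 scale, a value set from the difference between the VCaP arrays. The size rule was tested on simulated arrays of 34688 entries with a noise SD of 0.15 on the log2 scale and 200 changed genes per comparison. The changed genes were drawn from detected genes brighter than the median, so recovery of dim genes was not tested. The noise was also below the 0.29 used for the chance overlap. The values that follow may therefore be too favourable for these arrays. Simulated changes of 2 on the log2 scale were recovered at 100% in each comparison. Changes of 1.3 were recovered at 89% for ERG knockdown in VCaP, 93% for ERG overexpression in LNCaP and 86% for LEF1 knockdown, and 51, 42 and 97 unchanged entries passed. The alternatives tried were the table without normalization scaled to equal medians over the 7020 genes detected on all arrays, log2 of the signal plus 50, a detection p-value under 0.05, no brightness minimum, a minimum at the median, detection on both arrays, the probe table and other fold thresholds. Counting a gene as present by its detection p-value or by a signal at or above the brightness minimum was added after the data were examined. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.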

Results

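Gene expression was compared on 5 arrays from 2 prostate cancer cell lines, 1 array per group. VCaP carries the TMPRSS2-ERG fusion, in which an androgen-driven promoter expresses the ETS transcription factor ERG. LNCaP is an androgen-responsive line without that fusion. VCaP was measured with control siRNA and with siRNA against ERG. LNCaP was measured with a LacZ control, with ERG overexpression and control siRNA, and with ERG overexpression and siRNA against LEF1, a transcription factor through which Wnt and beta-catenin act on their target genes. Between 8587 and 10920 genes were detected per array. No group had a replicate, so no difference has a replicate check, no p-value is given, and the number of arrays limits the precision of every value.

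The targeted genes could not check the labels. ERG, on chromosome 21, was not detected on any of the 5 arrays. Its single entry (NM_182918.2) had signals of 6.9 on the VCaP control array and 7.4 on the VCaP siERG array, and of -0.3, -0.5 and -1 on the LNCaP LacZ, ERG and siLEF1 arrays. VCaP is known to express ERG, so this entry reports neither the knockdown nor the overexpression. LEF1, on chromosome 4 (NM_016269.2), was bright in VCaP, with signals of 645.1 on the control array and 823.7 on the siERG array. LEF1 was therefore 1.28-fold higher on the siERG array, a log2 fold of 0.35. In LNCaP, LEF1 was not detected on any array, with signals of 5 on LacZ, 12 on ERG and 3.9 on siLEF1. It has no fold there, so neither the effect of ERG overexpression on LEF1 nor the LEF1 knockdown could be measured. The arrays are named by their labels from here on.

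**Figure D1:**
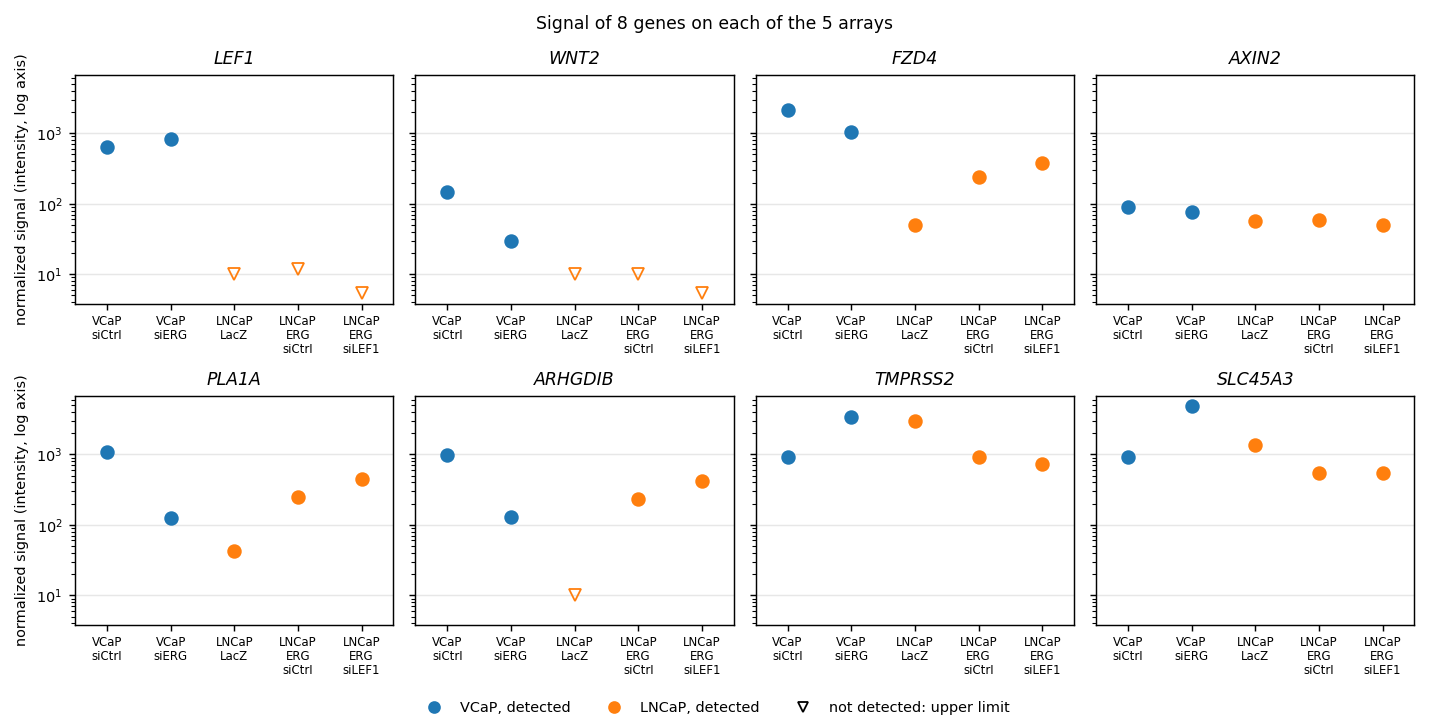
Quantile-normalized signal (log axis) of 8 genes on each of the 5 arrays, with VCaP in blue and LNCaP in orange. Filled circles are detected signals and each symbol is 1 array. Open triangles are nominal upper limits for genes that were not detected. They are drawn at the higher of the gene's own signal and the lowest detected signal of the array. LEF1 and WNT2 were detected in VCaP and not in LNCaP, and PLA1A and ARHGDIB were brighter on the ERG arrays than on the siERG or LacZ array of the same line.

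The VCaP pair asks which genes differ when the endogenous fusion-driven ERG is targeted. On the siERG array, 10 of 21 detected androgen-induced genes and 12 of 15 genes of cholesterol and fatty acid synthesis were at least 1.5-fold higher, while 5 of 22 cell cycle genes and 5 of 13 genes linked to ERG before were lower. By size, 142 genes were at least 2-fold higher and 143 at least 2-fold lower, of 10858 with a fold. Of these, 24 and 28 rest on a lower limit, and 18 and 12 carry provisional names.

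The lowest gene on the siERG array was REG4, a secreted lectin of the regenerating family, at 57.5-fold lower (signals of 1287.9 and 22.4). The siERG signal only just passed as detected (detection p-value 0.00779), so the size of this fold is uncertain. PLA1A, a phospholipase, was 8.52-fold lower and ARHGDIB was 7.75-fold lower. EPAS1, which encodes the hypoxia factor HIF-2alpha, was 8.57-fold lower, ANXA1 7.59-fold lower, the sulfate-donor enzyme PAPSS2 6.82-fold lower and GUCA2A 6.13-fold lower. TGM4, a prostate transglutaminase, was at least 10.2-fold lower, D4S234E (now NSG1) at least 9.46-fold, the calcium-binding S100P at least 8.36-fold, the engulfment adaptor GULP1 at least 7.41-fold, and CXCR7 (now ACKR3), an atypical chemokine receptor, at least 5.91-fold. In the other direction, the zinc transporter SLC30A4 was 5.54-fold higher and SLC45A3, a prostate transporter gene that also takes part in ERG fusions, was 5.29-fold higher (915.7 and 4846.4). SLC30A4 was dim on the control array, at 14.2 with a detection p-value of 0.00653, so its fold is uncertain in size too. HPGD, which inactivates prostaglandins, was 4.45-fold higher, MAGEH1 4.11-fold, the relaxin gene RLN1 4.04-fold, and BAMBI, a decoy receptor of TGF-beta signalling, 3.48-fold. TMPRSS2, the androgen-regulated protease whose promoter drives the fusion, was 3.67-fold higher, from 925.8 to 3395.5. The noncoding NCRNA00161 was 5.06-fold higher. LAMB2, a laminin chain, was at least 6.74-fold higher, GNMT at least 4.58-fold, the magnesium transporter SLC41A1 at least 4.56-fold and FKBP1B at least 4.21-fold.

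Of 21 detected androgen-induced genes, 10 were at least 1.5-fold higher on the siERG array and 0 were lower, with a median log2 fold of 0.58. They include SLC45A3, HPGD and TMPRSS2. Of 15 detected genes of cholesterol and fatty acid synthesis, 12 were higher and 0 lower, with a median of 0.77. They include IDI1 at 2.31-fold, HMGCS1 at 2.25-fold and LSS at 2.01-fold, enzymes of the mevalonate and sterol pathway. Cell cycle genes had a median of -0.47, and each of the 22 detected members was dimmer on the siERG array, 5 of them by at least 1.5-fold. MCM5, of the replicative helicase, was 2.07-fold lower and TYMS, thymidylate synthase, 1.90-fold lower. MCM7 was at least 1.63-fold lower, and MKI67 at least 2.55-fold lower, though the latter stayed under the brightness minimum. These 3 lists lay outside the middle 95% of random lists.

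Genes linked to ERG before had a median of -0.60 over 13 detected members, also outside the middle 95% of random lists. Of them 5 were lower, among them PLA1A, ARHGDIB and the transcriptional coactivator YAP1 (at least 5.85-fold), and 2 were higher, HPGD, which the androgen-induced list also holds, and the metalloprotease ADAMTS1 (3.08-fold). The 3 detected mesenchymal genes had a median of -0.94, with the cadherin CDH2 at least 4.45-fold lower, ACTA2 1.92-fold lower and TNC at a log2 fold of 0.03. Of 4 androgen-repressed genes, DDC was 5.54-fold lower and NOV 1.61-fold higher, while OPRK1 and MET had log2 folds of 0.56 and 0.36, and the median was 0.46. The NF-kB and inflammatory genes had a median of -0.43 over 5 members, with CCL2 1.65-fold lower, and NFKB1, BIRC3 and IL8 at log2 folds of -0.51, -0.43 and -0.13. These 3 medians lay outside the middle 95% of random lists. The mesenchymal median became 0.03 with a detection p-value under 0.05, and the androgen-repressed median became 0.21 with log2 of the signal plus 50 and then lay inside the middle 95%.

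Wnt components went both ways on the VCaP arrays and none of their lists lay outside the middle 95% of random lists. WNT2, a Wnt ligand, was 4.87-fold lower on the siERG array (144.6 and 29.7). Its receptor family member FZD4 was 2.04-fold lower (2122 and 1040.9), while FZD9 was 2.19-fold higher. The corepressor TLE1 was 2.60-fold lower. Among Wnt target genes, MYC was 2.03-fold lower and CCND1, cyclin D1, 1.55-fold higher, and the list median was 0.23. The medians were -0.31 for 3 Wnt ligands, -0.14 for 9 receptors, -0.23 for 7 inhibitors and 0.19 for 12 genes of the beta-catenin core. Medians of epithelial genes (0.18), neuroendocrine markers (-0.19), ETS factors (0.08), interferon response (-0.03), p53 targets (0.0031), stress genes (-0.0047), hypoxia and glycolysis (-0.05), polyamine metabolism (0.01) and housekeeping genes (-0.03) lay inside the middle 95%. Within these lists the neuroendocrine factor INSM1 was 3.46-fold lower, FAS 2.22-fold lower, ADM 2.04-fold lower and ANKRD37 2.46-fold higher.

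The LNCaP pair of ERG and LacZ arrays asks which genes differ when ERG is added to a line without the fusion. On the ERG array, 6 of 7 detected interferon-response genes, 4 of 12 genes linked to ERG before and 4 of 6 mesenchymal genes were at least 1.5-fold higher. Lower were 17 of 19 cell cycle genes and 5 of 20 androgen-induced genes. With respect to ERG, the cell cycle median had the opposite sign to that in VCaP, a difference that was not tested. At least 2-fold higher were 800 genes and at least 2-fold lower 564, of 10354 with a fold. The LacZ array was the dimmest and detected the fewest genes, and 345 of the higher genes and 61 of the lower genes rest on a lower limit. The ERG array is labelled with a control siRNA and the LacZ array's labels name none, so ERG and siRNA treatment cannot be separated in this pair.

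The 12 highest named genes were all undetected on the LacZ array. Their folds are set against the lowest detected signal there, 10.2, or their own signal where higher, so the actual folds can be smaller. CD24, a surface glycoprotein gene with near-identical copies elsewhere in the genome, was at least 44.7-fold higher, TMEM158 at least 40.3-fold, the protease inhibitor SLPI at least 38.9-fold and GDPD5 at least 34.4-fold. PPP1R15A, a stress-induced phosphatase subunit, was at least 24.7-fold higher, the trefoil factor TFF1 at least 24.5-fold, TBC1D3G at least 24.1-fold, ARHGDIB at least 22.6-fold, RARRES3 (now PLAAT4) at least 21.8-fold and ID2, an inhibitor of DNA-binding proteins, at least 20.8-fold. A pair of interferon-regulated genes completed this group, IFIT2 at least 22.9-fold and the factor IRF1 at least 22.1-fold higher. The 12 lowest were all undetected on the ERG array. The mitotic kinase genes BUB1 and AURKB, both in the cell cycle list, were at least 14.1-fold and 12.7-fold lower. CDCA2 was at least 12.8-fold lower, ANLN at least 10.7-fold, KIF2C at least 10.1-fold, CKAP2L at least 9.96-fold, GPSM2 at least 9.84-fold and KIF4A at least 9.49-fold. FANCI and RAD54L, which take part in DNA repair, were at least 14.6-fold and 10.5-fold lower. The neuropeptide gene NMU was at least 14.0-fold lower and CNTNAP2 at least 9.90-fold.

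Cell cycle genes had a median log2 fold of -1.69 over 19 detected members. Each of the 19 was dimmer on the ERG array and 17 were lower by the size rule. CENPA was at least 7.83-fold lower and CDC2 (now CDK1) at least 5.6-fold. Interferon-response genes had a median of 1.71 over 7 detected members, 6 of them higher and 0 lower. IFIH1, a sensor of double-stranded RNA, was at least 8.46-fold higher, IFI44 at least 7.05-fold and IFI6 3.28-fold. Genes linked to ERG before had a median of 1.18 over 12 members, 4 higher and 2 lower. PLA1A was 5.89-fold higher (42.4 and 249.6) and FZD4 4.73-fold higher (50.5 and 238.7). The potassium channel subunit KCNS3, at least 3.01-fold higher, stayed under the brightness minimum. Over members detected on both arrays this median was 0.29 and lay inside the middle 95% of random lists. Mesenchymal genes had a median of 1.25 over 6 members, 4 of them higher, among them COL5A1 at least 6.75-fold, TNC at least 2.81-fold and the integrin ITGA5 2.5-fold. TWIST1 was at least 2.02-fold lower, under the brightness minimum. Only ITGA5 and ACTA2 were detected on both arrays, too few for a median, so this median rests mostly on lower limits. Most of the 22 members were not detected, among them VIM, CDH2, FN1 and ZEB1.

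Androgen-induced genes had a median of -0.41 over 20 detected members, 5 lower and 1 higher. TMPRSS2 was 3.23-fold lower on the ERG array (2940.5 and 911.7), the kallikrein KLK2 2.79-fold lower, SLC45A3 2.51-fold lower and KLK3, which encodes prostate-specific antigen, 2.30-fold lower. These 5 lists lay outside the middle 95% of random lists, as did the Wnt target genes, with a median of 0.84 over 10 members, 3 higher and 2 lower. ID2 (at least 20.8-fold), JUN (2.77-fold) and SOX9 (2.75-fold) were higher, and MYC (1.92-fold) and CCND1 (1.58-fold) were lower. Over Wnt targets detected on both arrays the median was -0.23, so its sign rests on genes at their lower limit. No Wnt ligand was detected with a fold in LNCaP. Receptors had a median of 0.12 over 8 members, Wnt inhibitors 0.30 over 6 and the beta-catenin core 0.36 over 13, all inside the middle 95%. In the core list 5 genes were higher and 0 lower, among them TLE1 at 3.37-fold and the Dishevelled gene DVL2 at 2.86-fold.

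The other lists lay inside the middle 95% with medians of 0.22 for ETS factors, 0.16 for epithelial genes, 0.46 for neuroendocrine markers, 0.33 for endothelial markers, 0.40 for NF-kB genes, 0.40 for p53 targets, -0.0039 for stress genes, -0.21 for hypoxia and glycolysis, -0.12 for cholesterol and fatty acid synthesis, -0.25 for polyamine metabolism and -0.15 for housekeeping genes. Within these lists the stress factor DDIT3 was 6.34-fold higher while ASNS, asparagine synthetase, was 2.82-fold lower. Epithelial genes went both ways, with 6 higher and 2 lower of 15 detected. KRT8 and CLDN7 were 2.66-fold and 2.11-fold higher, while KRT19 was 2.04-fold lower but under the brightness minimum. KRT18 and CLDN3, named after their values were seen, were 1.84-fold and 1.55-fold lower. Of the ETS factors, ETV6 was 2.75-fold higher, and EHF and SPDEF were 2.16-fold and 2.14-fold lower. The polyamine enzymes SRM and ODC1 were 3.38-fold and 2.13-fold lower. Among housekeeping genes, TFRC was 1.99-fold lower and B2M 1.83-fold higher.

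**Figure D2:**
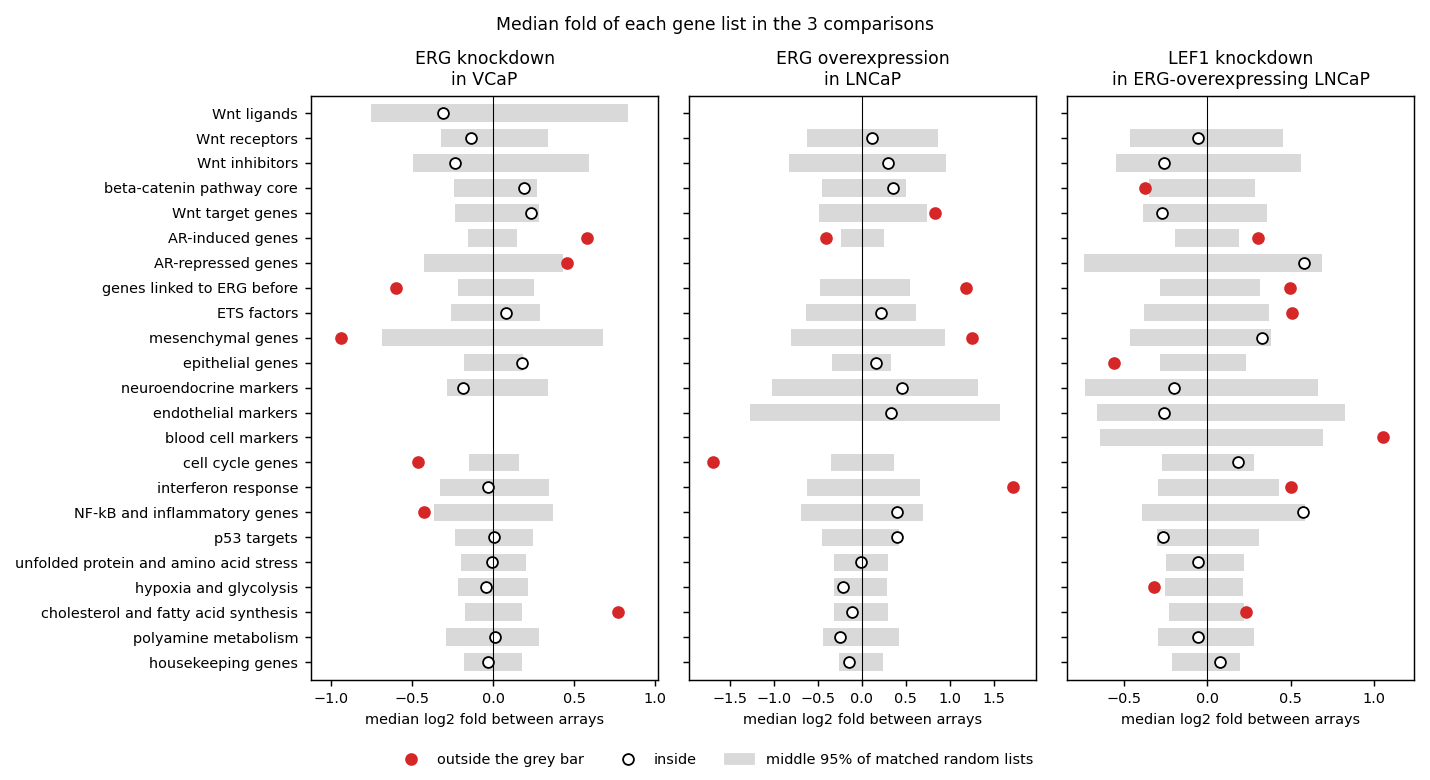
Median log2 fold of each gene list (points) in the 3 comparisons, with the middle 95% of 10000 random lists matched on mean signal as grey bars. Red points lie outside their bar and white points inside it, and lists with under 3 detected members are left out. Cell cycle genes had medians of -0.47 on ERG knockdown in VCaP and -1.69 on ERG overexpression in LNCaP.

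The siLEF1 and control siRNA arrays of ERG-overexpressing LNCaP ask which genes differ when LEF1 is targeted in the presence of ERG. On the siLEF1 array, 7 of 15 detected epithelial genes and 3 of 12 genes of hypoxia and glycolysis were at least 1.5-fold lower. Higher were 6 of 14 genes linked to ERG before and 3 of 10 interferon-response genes, and the interferon median lay inside the middle 95% of random lists (0.26) over members detected on both arrays. In all, 245 genes were at least 2-fold higher and 194 at least 2-fold lower, of 11472 with a fold, and 108 and 10 of them rest on a lower limit. The siLEF1 array was the brightest before normalization and detected the most genes.

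The lowest named gene was FOS, an immediate-early transcription factor, at least 11.3-fold lower on the siLEF1 array. The lysosomal protease CTSZ was at least 7.78-fold lower, FKBP10 at least 6.21-fold, the scaffold gene DLG4 at least 5.87-fold and DTNB at least 5.71-fold. AP2B1, a clathrin adaptor subunit, was 6.55-fold lower, NDUFA4L2, a hypoxia-responsive mitochondrial gene, 6.21-fold, NDST1, a heparan sulfate enzyme, 6.12-fold, COPG2 5.94-fold, DLST 5.32-fold, OAZ2 5.17-fold and the kinase DAPK3 4.76-fold. Highest was S100A3, at least 7.5-fold. UGT2B28, which conjugates androgens, was 6.19-fold higher, LXN 5.50-fold, the secretoglobin SCGB2A2 5.48-fold and S100P 4.68-fold. The chemokine CCL20 was at least 5.44-fold higher, the cystine transporter SLC7A11 at least 5.19-fold, ZNF679 at least 5.10-fold, TRUB1 at least 4.79-fold, DKFZP564O0523 (now RBM48) at least 4.66-fold and TBC1D23 at least 4.61-fold.

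Epithelial genes had a median log2 fold of -0.56 over 15 detected members, 7 lower and 1 higher. ST14, the protease matriptase, was 2.23-fold lower, the junction genes CGN and JUP 1.77-fold and 1.75-fold lower, and KRT8 1.76-fold lower. The higher gene was EPCAM, at 1.64-fold, named after its value was seen. Hypoxia and glycolysis genes had a median of -0.32 over 12 members, with PFKFB4 2.25-fold, PFKFB3 2.04-fold and ENO1 1.56-fold lower and EGLN3 1.5-fold higher. Genes linked to ERG before had a median of 0.50 over 14 members, 6 higher and 1 lower, with HPGD 2.31-fold, PLA1A 1.81-fold and ARHGDIB 1.80-fold higher. Interferon-response genes had a median of 0.50 over 10 members, 3 higher and 0 lower, with IFIH1 2.35-fold and IFI44 1.83-fold higher. Androgen-induced genes had a median of 0.30 over 22 members, 5 higher and 2 lower, with HPGD higher and the kinase CAMKK2 1.83-fold lower. ETS factors had a median of 0.51 over 10 members, 2 higher and 0 lower, with EHF 1.75-fold higher. Cholesterol and fatty acid synthesis had a median of 0.23 over 16 members, with SQLE 1.59-fold and IDI1 1.57-fold higher and MVD 1.56-fold lower. Blood cell markers, a list for another cell type, had a median of 1.05 over 4 detected members, 3 higher and 0 lower, with S100A9 2.25-fold, the globin HBA2 1.61-fold and HBA1 at least 3.34-fold higher. These 8 lists lay outside the middle 95% of random lists, as did the beta-catenin core described next. Over members detected on both arrays, the ETS median was -0.12 and the androgen-induced median 0.11, each inside the middle 95%, and the cholesterol median lay inside it under every alternative run.

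For Wnt components, no ligand was detected with a fold and the lists showed small medians on the siLEF1 array. The beta-catenin core had a median of -0.37 over 13 members, 2 lower and 0 higher, outside the middle 95%. The corepressor TLE3 was 2.46-fold lower and PYGO2, a beta-catenin coactivator, 1.92-fold lower. Over members detected on both arrays the median was -0.18 and inside the middle 95%. Wnt target genes had a median of -0.27 over 11 members, with 1 gene, ID2, at least 1.5-fold higher (1.65-fold) and 0 lower, and this list lay inside the middle 95%. So did the receptors (median -0.05; FZD4 1.60-fold higher and FZD3 1.62-fold lower) and the Wnt inhibitors (-0.26). Medians of 0.18 for cell cycle genes, 0.57 for NF-kB genes, 0.58 for androgen-repressed genes, 0.33 for mesenchymal genes, -0.20 for neuroendocrine markers, -0.26 for endothelial markers, -0.27 for p53 targets, -0.05 for stress genes, -0.06 for polyamine metabolism and 0.08 for housekeeping genes also lay inside the middle 95%. Within these lists ENO2 was 2.86-fold lower, TNC 1.75-fold higher and CDC2 at least 2.43-fold higher.

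Genes were next compared between the 2 cell lines, which share no array. At 1.5-fold, 79 genes were lower on the siERG array in VCaP and higher on the ERG array in LNCaP, where 51.6 would be found if the lists were independent. They were led by ARHGDIB, PLA1A, GALNTL4 (now GALNT18), APOD, IGFBP3, TMEM158, MGP and PLA2G2A. APOD, an apolipoprotein, was 4.89-fold lower on the siERG array and 8.61-fold higher on the ERG array, and IGFBP3, which binds insulin-like growth factors, was 4.37-fold lower and 5.23-fold higher. The reverse combination, higher on siERG and lower on ERG, held 57 genes against 53.7, led by TMPRSS2, RLN2, SLC45A3, ELMOD2, SPRYD5, CCDC136, TMEFF2 and SLC30A4. Genes higher in both comparisons numbered 81 against 54.9, led by GNMT, HIST2H2BE (now H2BC21), ENPP5, TP53INP2, TUBB3, PLXNA3, WIPI1 and CYTH1. Lower in both were 69 genes against 50.5, led by S100P, CXCR7, SNHG4, IPO5, HMMR, MCM5, LMAN2 and MYC. Each combination exceeded its count for independent lists. Those counts include dim genes that the brightness minimum bars from passing, so they may be too low. Across the 8814 genes with a fold in both lines, Spearman's correlation of the folds was 0.10, where opposite effects of knockdown and overexpression would give a negative value. Genes are not independent replicates, so this correlation has no p-value.

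**Figure D3:**
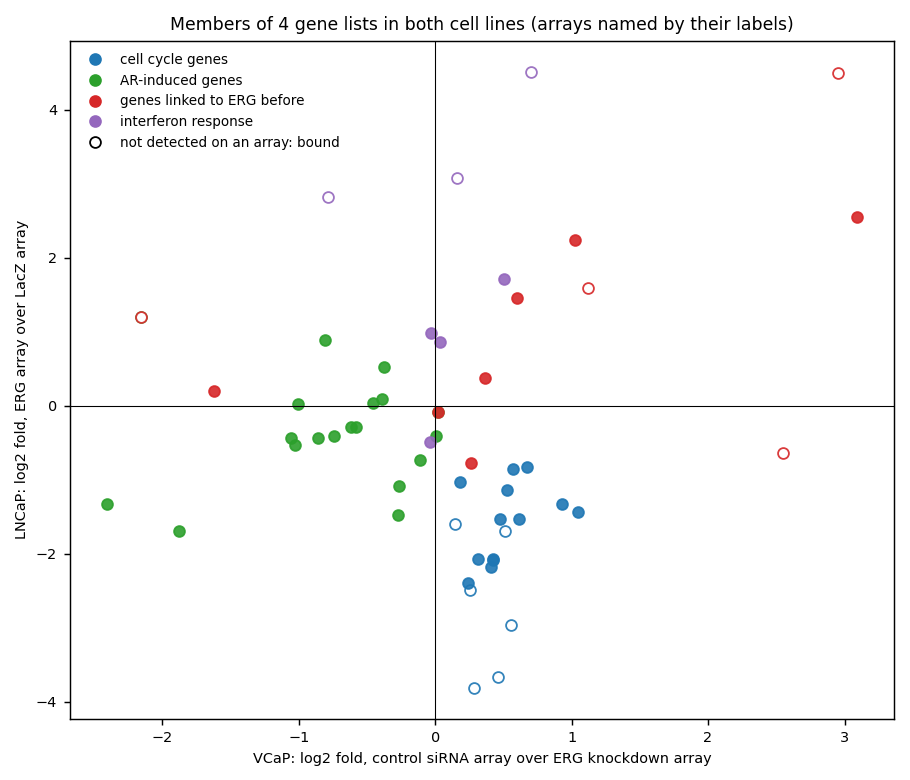
Members of 4 gene lists with a fold in both lines: the horizontal axis is the log2 fold of the VCaP control array over the siERG array and the vertical axis that of the LNCaP ERG array over the LacZ array. Each point is 1 gene, and open points are genes not detected on at least 1 array, at nominal limits. Cell cycle genes lie at the lower right, brighter on the VCaP control array and dimmer on the LNCaP ERG array, while PLA1A and ARHGDIB lie at the upper right.

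Genes higher with ERG and lower with LEF1 knockdown in LNCaP numbered 269, where independent lists would share 125. Here too the count for independent lists includes dim genes that could not pass, so it may be too low. FOS, DLG4, DAPK3, MED12, MYO1G, ATHL1 (now PGGHG), SCAMP5 and RCOR2 led them. FOS was at least 13.6-fold higher on the ERG array than on LacZ and at least 11.3-fold lower on siLEF1. Lower with ERG and higher with LEF1 knockdown were 156 genes against 89.3, led by FANCI, CLDN8, NDC80, S100P, RFC3, DTL, CHEK1 and CDC2. Both comparisons contain the ERG array with control siRNA in opposite roles, which gives such overlap without any effect. With no effect, 100 simulated sets of 3 arrays gave a mean of 207 genes higher and then lower, with a range of 171 to 258. The simulated lists were smaller, with means of 629 genes higher and 634 lower, against 1502 and 836 observed. The overlap counts are therefore not like for like. The covariance of the folds was -0.0863 observed and -0.0836 simulated, and Pearson's correlation was -0.19 observed and -0.50 simulated. A correlation near -0.50 follows from the setting of the simulation, equal noise on 3 arrays. The simulated covariance likewise follows from the noise put in, which was set from the VCaP arrays. Its nearness to the observed value therefore says nothing about noise on the LNCaP arrays. Over the 7744 genes detected on all 3 LNCaP arrays the observed covariance was -0.0523. Part of the overlap may come from the shared array, and with 1 control array it could not be split. Genes higher in both numbered 103 against 107, led by PI3, TFF1, ID3, HIST1H2AC (now H2AC6), MGP, IGFBP6, IFIH1 and HIF1A, and lower in both were 69 against 105, led by LMNB1, TAF15, SSRP1, NUP210, ZNF395, HAUS4, TGM3 and DLST.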

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

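The tests on the ERG array with control siRNA alone and on the LacZ array alone were chosen after the results were seen. Cell cycle genes stood in opposite directions with respect to ERG in the 2 cell lines. Their median log2 fold was 0.467 for the VCaP control array over the siERG array and -1.69 for the LNCaP ERG array over the LacZ array. All 22 detected members in VCaP and all 19 in LNCaP went with their median. With 1 array per group the difference between the lines was not tested. Of the lists that lay outside the middle 95% of random lists in both lines, this was the 1 list with opposite signs.

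The tables argue against several technical sources of the LNCaP value. If quantile normalization of arrays of unequal brightness had produced it, the list would lie inside the middle 95% without that step. In the table without quantile normalization its median was -1.63, below all 10000 random lists. That table scales the same signals by a single factor per array, so dimness of the LacZ array itself was not tested. Dim genes placed at the detection floor are not needed for it, since members detected on both arrays had a median of -1.53. The ERG array alone is not enough either: the siLEF1 array over LacZ gave -1.59, again below all random lists. What stays open is the LacZ array, because the series has 1 LNCaP array without ERG, and a faster-growing culture behind that array cannot be told apart from an effect of ERG or of the control siRNA. A biological difference between the lines, one with endogenous and one with added ERG, was not tested.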

How the results depend on the processing

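Counts by size depended on the rule, and directions mostly did not. The table without normalization, scaled to equal medians, and the added setting of presence by signal kept all 8 counts within 1.5 times. The values below give genes higher and then lower for ERG knockdown in VCaP, ERG overexpression in LNCaP and LEF1 knockdown, and they name a count where it moved by more. At 1.5-fold they were 510 and 473, 1502 and 1270, and 849 and 836. With the brightness minimum at the median they were 61 and 65, 419 and 323, and 76 and 92, and with no minimum 377 and 322, 1322 and 951, and 511 and 434. With log2 of the signal plus 50, which shrinks folds of dim genes, they were 36 and 49, 390 and 251, and 27 and 30. With a detection p-value under 0.05 they were 223 and 248 in VCaP, 878 lower with ERG in LNCaP, and 470 and 319 with LEF1 knockdown. Detection on both arrays left 455 genes higher with ERG in LNCaP and 137 higher with LEF1 knockdown. Among probes of the further table, 215 were higher in VCaP, 852 lower with ERG in LNCaP, and 528 and 321 higher and lower with LEF1 knockdown. The 79 genes lower on siERG and higher on ERG became 24 at 2-fold, 37 with the median minimum, 175 with none, 31 with the signal plus 50, 143 with the looser detection p-value and 52 with detection on both arrays. The 269 genes higher with ERG and lower with LEF1 knockdown became 38, 138, 506 and 90 under the first 4 of these settings, 176 with detection on both arrays and 405 among probes. The probe table has no detection p-values and several probes per gene, so its counts run over other items.

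Of the 22 list medians outside the middle 95%, 107 recomputed values included 90 on the same side, 14 inside the middle 95% and 3 with the other sign. With detection on both arrays, the medians became -0.23 for Wnt targets and 0.29 for genes linked to ERG before on ERG overexpression, and -0.12 for ETS factors, -0.18 for the beta-catenin core, 0.11 for androgen-induced genes, 0.26 for interferon and 0.17 for cholesterol genes on LEF1 knockdown. The setting leaves fewer genes, those without a lower limit. With a detection p-value under 0.05 they became 0.034 for mesenchymal genes in VCaP and 0.17 for cholesterol genes on LEF1 knockdown. With the signal plus 50 they became 0.21 for androgen-repressed genes in VCaP, and 0.19 for ETS factors and 0.11 for cholesterol genes on LEF1 knockdown, which were also 0.11 in the scaled table. Presence by signal, added after the data were examined, gave 0.29 for androgen-repressed genes in VCaP, 0.13 for Wnt targets on ERG overexpression, and -0.31 for the beta-catenin core and 0.077 for cholesterol genes on LEF1 knockdown. Of 198 recomputed medians of the other lists, 9 came to lie outside the middle 95%. Beyond the makeup of the settings, the cause was not tested. LEF1 in VCaP had log2 folds of 0.34 in the scaled table and 0.33 with the signal plus 50. Of 314 recomputed folds of 72 named gene results, 243 moved little, 71 moved and 0 changed sign, 63 of the moved ones with the signal plus 50. Part of this was fixed in advance. The naming rule required the same direction in the scaled table, which gave 72 of the values. The 26 values with detection on both arrays are the main folds themselves. The named genes are also the most extreme ones, so their stability does not speak for other genes. ERG in both lines and LEF1 in LNCaP gave no fold under any setting, because no array detected them. Single genes and lists could not be followed in the probe table, which carries no gene names. No paired analysis was possible because each group has 1 array. Signal over background limits the dim genes, and the LacZ array detected the fewest genes. A fold from an undetected array is a lower limit only with respect to the signal put in its place.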

Other observations

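The lines differed in which Wnt components the arrays detected at all. These genes were chosen after their values were seen, and levels are given per array, since no array pair here compares the lines. In VCaP, LEF1 (645.1 and 823.7 on the control and siERG arrays), the receptor LGR4 (119.5 and 108.8), FZD8 (43.2 and 31.2) and WNT3 (31.6 and 33) were detected on both arrays, and in LNCaP none of the 4 was detected on any array. All 4 go towards VCaP, and genes that go the other way are not named here. The beta-catenin core list had 12 detected members in the VCaP comparison and 13 in each LNCaP comparison, so the difference did not run only towards VCaP. The other LEF1 family members TCF7, TCF7L1 and TCF7L2 were not detected on any of the 5 arrays, with signals from -17.4 to 11. An undetected entry does not show that a gene is absent, since ERG was also undetected in VCaP, which is known to express it. AXIN2, a common readout of beta-catenin activity, was detected on all 5, at 90.5 and 76.9 in VCaP and at 57.5, 59.5 and 49.4 on the LacZ, ERG and siLEF1 arrays of LNCaP. FZD4, at 2122 and 1040.9 in VCaP, was at 50.5, 238.7 and 382.1 in LNCaP and thus brightest in that line on the siLEF1 array.

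Markers of other cell types were mostly not detected. No basal epithelial marker was detected with a fold in any comparison. Of 14 endothelial markers 2 to 4 were detected, among them ENG, 1.95-fold lower on the siERG array in VCaP, and VWF, with log2 folds of -0.14 on the ERG array and -0.51 on the siLEF1 array of LNCaP. Blood cell markers were an exception in LNCaP. Besides the 3 genes higher on the siLEF1 array than on the ERG array, S100A8 was at least 1.91-fold higher but under the brightness minimum. HBA2 was also at least 11.1-fold higher on the ERG array than on LacZ. The leukocyte genes PTPRC, CD3E, CD14 and LYZ of the same list were not among the detected members, and in VCaP HBA2 was detected at 57.8 and 45.7.

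Between the lines, 34 genes were at least 2-fold in the same ERG direction and 18 in opposite directions, counts with no chance value. The excess was not kept at 1.5-fold, where the report's counts are 79 and 57 genes in the same direction and 81 and 69 in opposite directions, so neither direction is taken as the rule. The 18 included S100P, brighter by at least 8.36-fold on the VCaP control array than on siERG and 3.0-fold dimmer on the LNCaP ERG array than on LacZ, and CXCR7, HMMR and MCM5 with the same signs. ENPP5, TUBB3 and PLXNB1 had the reverse signs. Genes chosen in VCaP alone, at least 1.5-fold lower on siERG, had a median of -0.10 on ERG overexpression in LNCaP, below the middle 95% of random lists, although 79 of them were at least 1.5-fold higher and 69 lower. On the siLEF1 array over LacZ, where ERG is also overexpressed, their median was -0.04, inside the middle 95%. Genes at least 1.5-fold higher on siERG had a median of 0.085 on ERG overexpression and of 0.098 on siLEF1 over LacZ. Both lay above the middle 95% of random lists.

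The test of the control siRNA below was chosen after the result was seen. Interferon-response genes were higher on the ERG array than on the LacZ array. A hypothesis is that quantile normalization of arrays of unequal brightness produced this. In the table without that step the median was 1.79, above all 10000 random lists, which argues against it. Dimness of the LacZ array itself remains in that table and was not tested. A second candidate explanation is the control siRNA or its delivery, since double-stranded RNA can induce such genes and the sensor IFIH1 was among them. However, only 7 of the 22 list members were detected. MX1, OAS1, OAS2, OAS3 and IFIT3 were detected on neither the ERG nor the LacZ array. IFIT1 was also undetected on both, at signals of 55.2 on ERG and 8.1 on LacZ. Missing detection therefore does not show that a gene was not induced. With 0 LNCaP arrays that carry a control siRNA without ERG, ERG and siRNA cannot be told apart, and 1 LacZ array leaves its own state open too. In VCaP, where both arrays are labelled with an siRNA, the interferon median was -0.03.

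Genes higher with ERG and lower with LEF1 knockdown in LNCaP were more frequent than independent lists would give, and the hypothesis was that LEF1 carries part of the ERG response. The count for independent lists may be too low, as it includes dim genes that could not pass. Noise of the shared array is a candidate explanation. Genes chosen in VCaP alone as lower on siERG had a median of 0.068 on LEF1 knockdown, at percentile 99.5, and genes chosen as higher on siERG had one of 0.051, at percentile 98.7. The shift was thus not specific to either direction, and the first set had no median above that of random lists with ERG in LNCaP, so this leaves the question open. Simulated arrays with no effect and noise as large as the whole VCaP difference gave at most 258 genes, against 269 observed. The simulated lists were also much smaller than the observed ones, so these counts are not like for like. The prediction written beforehand took any smaller simulated number as evidence against noise, which was wrong because the noise of the LNCaP arrays is unmeasured and 258 lies close to 269. LEF1 was not detected on any LNCaP array, so neither a rise with ERG nor its knockdown is shown. Noise, an effect of LEF1 and any other difference between the siLEF1 and ERG arrays cannot be told apart here.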
